A study of Rattus norvegicus with 8 samples.

How the data were processed

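RNA was measured in the lateral and basal nuclei of the rat amygdala, cut out by laser microdissection on the side of the electrode. The 8 Affymetrix rat genome arrays fall into 4 groups of 2, and within each group the arrays carry the letters A and B. Each array held amplified RNA pooled from 2 of a group's 4 rats, so that 16 rats are represented. The labels call the arrays biological replicates and do not say what A and B stand for. The design text and the protocols of the single samples give different section thicknesses, stains and storage temperatures, and different amounts of amplified RNA per rat, and these details were not used here.

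The deposited value of a probe set is its signal intensity on a linear scale. Per the labels the authors made it with MAS5, whose version and scaling target are not stated. All values were above 0 (smallest 0.0266), and the median signal per array lay between 29.0 and 43.2. Pearson correlations between arrays ran from 0.846 to 0.963, and 0 pairs of arrays were identical. The number of arrays limits the precision. Detection calls were not used here, so a background level could not be set, and a gene is marked below where its lower group lay under the level of the filter on dim probe sets.

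Signals were transformed to log2 with no further normalization. The 57 control probe sets were left out. Of the other 31042 probe sets, 18625 had a mean log2 signal above the 40th percentile (log2 4.35, a signal of 20.3) and were tested. A probe set was named where the annotation gave a single gene symbol (20826 probe sets; 436 had several symbols and 9780 had none), which left 10364 named genes among those tested. A gene was read by its probe set with the highest mean signal. Genome positions were not used here.

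Differences were tested with limma 3.58.1 in R 4.3.3. A fit with 4 group means gave 7 comparisons, with an intensity trend in the prior variance, two-sided moderated tests and Benjamini-Hochberg adjustment over the 18625 probe sets at 0.05. Standard errors (SE) come from this fit, and standard deviations (SD) are between arrays. Gene lists were tested on the same fit by limma's camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, each adjusted over the 32 lists with at least 5 measured genes. Counts of list members that passed are given over all probe sets and adjusted over the list alone. Means of each list per array were compared with a two-sided exact permutation test over the 70 assignments of 4 against 4 arrays, which cannot give a p below 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

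The tests, the filter, the alternatives, the rule for naming genes and the 33 gene lists were chosen before the data were examined. Of 819 list entries, 715 have a probe set and 595 were tested. The lists cover reactive astrocytes, microglia and macrophages, antigen presentation, complement, the interferon response, cytokines and chemokines, lysosomes and cathepsins, extracellular matrix remodelling, oligodendrocytes and myelin, and endothelium and mural cells. They also cover excitatory neurons, GABAergic interneurons, GABA-A receptor subunits, ionotropic and metabotropic glutamate receptors, potassium channels, sodium, calcium and HCN channels, immediate early genes, synaptic vesicle release, the postsynaptic density, growth factors and neurotrophins, neuropeptides and their receptors, fear learning signalling, and cytoskeleton and axon growth. The rest cover cholesterol biosynthesis, oxidative phosphorylation, ribosomal proteins, heat shock and oxidative stress, cell death and survival, striatal and central amygdala neurons, blood cells, choroid plexus and ependyma, and meninges and fibroblasts. A further 7 lists, chosen after the data were seen, appear only among the closing observations, adjusted over all 38 testable lists.

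The rule for named genes takes the 12 largest increases and the 12 largest decreases among genes that passed and whose groups did not overlap (6 and 6 in the other comparisons). Where none passed, it takes the 3 smallest p in each direction as values only. It adds at most 4 passing genes per list, or the values of at most 2 where no member passed. Gfap, Cd74, Fos, Arc, Bdnf, Npy, Slc17a7 and Gad1 are always given.

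The letters were checked as a possible pairing of samples. Deviations of arrays from their group means correlated across probe sets between like letters at 0.321 to 0.407 in all 6 pairs of groups. The letter was therefore also entered as a block, with its value printed beside the counts of genes, and the comparisons were repeated within each letter. The unblocked fit stays the primary one because it was fixed beforehand. Alternatives were quantile normalization, median centring, an offset before the logarithm, no filter or a stricter filter (60th percentile), no intensity trend, array weights, fits to fewer arrays or factors, the mean of a gene's probe sets, and leaving out each array. The fits within a letter were added after the data were seen.

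The fit was tested on simulated data with 200 changed probe sets among 18625 in 3 runs for each comparison. For epileptogenic against control, 5.67% of 2-fold and 64.7% of 4-fold changes were recovered without the block, and 64.3% and 92.3% with it. For paired against unpaired training these shares were 5.33% and 60.7% without the block and 64.0% and 86.7% with it. Among control rats alone, 0% of 2-fold and 10.0% of 4-fold changes were recovered without the block, and 29.7% and 81.0% with it. The block also brought false calls. Their mean per run was 0 without it in each of these comparisons. With the block it was 15.7 for epileptogenic against control, 9 for training and 10.3 for training among control rats.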

Results

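Gene expression was profiled in the basolateral amygdala of rats in the days after status epilepticus, a prolonged seizure that starts the development of epilepsy. Epileptogenic rats had status epilepticus induced by stimulating the amygdala, and control rats carried an electrode without stimulation. On day 8 a tone (75 dB, 20 s) and a footshock (1.5 mA, 1 s) were given in 2 trials. In paired training the tone and the shock were coupled, as in fear conditioning, and in unpaired training they were not. Tissue was taken 3 h later. The rats formed 4 groups, each with 2 arrays (A and B) of 2 pooled rats: control unpaired, control paired, epileptogenic unpaired and epileptogenic paired. The median signal per array was between 29.0 and 43.2 intensity units.

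The comparison of 4 epileptogenic with 4 control arrays addresses how the amygdala's transcripts differ during epileptogenesis. Every rat had received the tone and the shock 3 h before. A lasting difference can therefore not be told apart from a different response to them. Genes of microglia, astrocytes and the immune response rose, while some neuronal genes fell. More probe sets were higher than lower without the replicate letter as a block (523 and 154), but not with it (1411 and 1611). With an estimated correlation 0 of 32 gene lists were called. Gfap, the intermediate filament of astrocytes, had a mean log2 signal of 11.92 ± 0.17 (SD, n = 4) in epileptogenic and 9.09 ± 0.76 in control arrays, 7.11-fold higher. Of 26 measured genes of microglia and macrophages, the brain's resident and invading phagocytes, 21 rose. Their mean per array, relative to the control mean, was between 1.82 and 2.20 on the log2 scale in epileptogenic arrays and between -0.66 and 0.40 in control arrays. Fos, an immediate early gene, rose by 1.70 ± 0.28 (SE; adjusted p = 0.0132), whereas Arc changed by a non-significant -0.25 ± 0.47 (adjusted p = 0.828).

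In limma, 677 probe sets passed, 523 higher and 154 lower in epileptogenic rats, covering 493 named genes. With the replicate letter as a block 3022 passed, 1411 higher and 1611 lower, among them all 677, so the share that was higher was 77.3% without and 46.7% with the block. Within letter A alone 755 passed and within letter B alone 1321, and the log2 changes within the 2 letters had a Pearson correlation of 0.622 across genes. Single arrays moved the count: it was 369 without control unpaired A, 350 without control unpaired B, 253 without control paired A and 406 without control paired B. It was 435 without epileptogenic unpaired A, 224 without epileptogenic unpaired B, 278 without epileptogenic paired A and 366 without epileptogenic paired B, and 182 of the 677 passed in all 8 of these fits. The median log2 difference over all tested probe sets was -0.11.

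The largest increases included genes of the interferon response and of phagocytes. Ddx60, an interferon-induced helicase, rose by 4.21 ± 0.71 (log2, SE; adjusted p = 0.0157) and Hspb1, a small heat shock protein, by 4.06 ± 0.55 (adjusted p = 0.00550). Rsad2, which encodes the antiviral protein viperin, rose by 3.40 ± 0.24 (adjusted p = 0.000950), Mx2 by 3.49 ± 0.46, Slfn4 by 3.80 ± 0.51 and Ifgga2l1 by 3.38 ± 0.21 (adjusted p = 0.000830). Cd68, a lysosomal protein of macrophages, rose by 3.98 ± 0.68, the Fc receptor gene Fcgr2b by 3.36 ± 0.35, Fcrl2 by 3.58 ± 0.38, Clec12a by 3.49 ± 0.71, Olr1, a receptor for oxidised lipoprotein, by 3.15 ± 0.60, and Tagap by 3.39 ± 0.74. In Ddx60, Hspb1, Cd68, Clec12a, Olr1 and Tagap the control mean lay under the filter level of 4.35, so these sizes rest on dim control signals. Single arrays carried part of them: without control paired A the change was 3.43 for Ddx60, 3.00 for Cd68 and 2.56 for Tagap, without control unpaired B 2.65 for Clec12a, and without epileptogenic paired B 2.49 for Olr1.

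The largest decreases were mostly smaller. Myo16 fell, with a log2 change of -3.26 ± 0.47 (SE; adjusted p = 0.00706), as did the transcription factor gene Zic2 with -2.56 ± 0.55 (adjusted p = 0.0378) and Nrarp, a regulator of Notch signalling, with -2.26 ± 0.24 (adjusted p = 0.00237). The log2 change of Trhr, the receptor of thyrotropin-releasing hormone, was -2.09 ± 0.44, and that of the neuronal globin gene Ngb -2.07 ± 0.40. Car4, Palmd, Adamtsl1, Plagl1, Tsga10, Ddn, which encodes the dendritic protein dendrin, and Hecw1 fell, with log2 changes between -1.74 and -1.45. The epileptogenic mean of Myo16, Zic2, Ngb and Car4 lay under the filter level. Of all 24 genes named by size, 9 passed with any single array left out: Fcgr2b, Fcrl2, Hspb1, Ifgga2l1, Mx2, Myo16, Nrarp, Rsad2 and Slfn4. The others lost the call in at least 1 of these fits, Hecw1 in 1 and Car4, Palmd, Plagl1, Tagap, Trhr and Tsga10 in 7 of the 8.

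**Figure D1:**
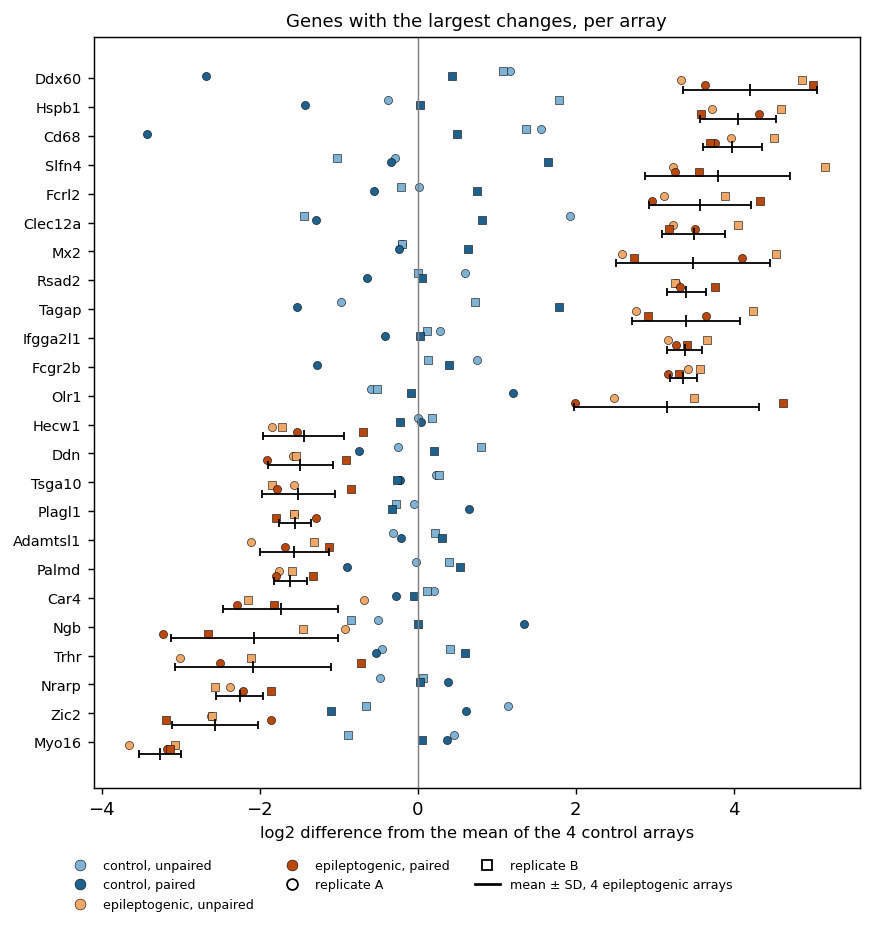
Log2 signal of the 24 genes with the largest changes on each of the 8 arrays (points; colours give the group, circles letter A and squares letter B), as the difference from the mean of the 4 control arrays, with bars for the mean ± SD of the 4 epileptogenic arrays. The epileptogenic arrays lie apart from the control arrays for each gene because the rule took only genes whose groups did not overlap. The epileptogenic means are 3.40 for Rsad2 and -2.26 for Nrarp.

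Most microglial and immune lists shifted upward. They are not fully separate, since 3 of 10 complement genes and 1 of 16 lysosomal genes also stand in the microglial list. In the microglia and macrophage list, 21 of 26 genes rose (24 adjusted over the list alone, 24 with the block), with a median log2 change of 1.92 and a camera adjusted p = 2.86e-27, against an adjusted p = 0.0618 with an estimated correlation. Ptprc, the leukocyte common antigen, rose by 2.89 ± 0.53 (log2, SE) and Aif1 by 2.72 ± 0.41, while a further probe set of Aif1 had the opposite sign and did not pass. Of 10 complement genes 9 rose (9 adjusted over the list alone, 9 with the block; median 1.91, camera adjusted p = 1.85e-12, adjusted p = 0.0618 with an estimated correlation), among them the inhibitor gene Serping1 at 3.12 ± 0.48 (2.47 without control paired A) and C1qb at 2.41 ± 0.52 (1.75 without control unpaired A). Of 19 interferon response genes 14 rose (15 adjusted over the list alone, 15 with the block; median 1.82, camera adjusted p = 8.41e-19, adjusted p = 0.0618 with an estimated correlation), among them Mx1 by 2.56 ± 0.32 from a control mean under the filter level and Isg15 by 2.18 ± 0.38. Of 16 lysosomal genes 13 rose (14 adjusted over the list alone, 14 with the block; median 1.52, camera adjusted p = 5.72e-19, adjusted p = 0.0618 with an estimated correlation), with Grn, which encodes progranulin, up by 2.56 ± 0.23 and the protease gene Ctsd by 2.15 ± 0.20. In antigen presentation, 6 of 15 genes rose (11 adjusted over the list alone, 8 with the block; median 1.40, camera adjusted p = 8.85e-09, adjusted p = 0.0620 with an estimated correlation), including B2m by 1.58 ± 0.16, but Cd74 showed 1.40 ± 0.55 and did not pass (adjusted p = 0.208), at 0.75 without epileptogenic unpaired A. Among 10 cytokine and chemokine genes, Il18 rose by 1.47 ± 0.27 (2 genes adjusted over the list alone), and the list itself did not pass camera (adjusted p = 0.0897). With the block 3 rose and 1 fell, and with single arrays left out 0 to 2 rose.

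Astrocytic and matrix genes rose too. These lists share genes as well: 4 of 16 astrocytic and 6 of 23 matrix genes also stand in another list, with Timp1 and Cd44 in both. Of 16 genes of reactive astrocytes 9 rose (10 adjusted over the list alone, 10 with the block; median 1.34, camera adjusted p = 6.63e-10, adjusted p = 0.0618 with an estimated correlation), among them the filament gene Vim by 2.10 ± 0.32 (log2, SE) and the adhesion receptor gene Cd44 by 2.98 ± 0.52 (2.35 without control paired A) from a control mean under the filter level. In extracellular matrix remodelling 7 of 23 rose (11 adjusted over the list alone, 11 with the block; median 0.81, camera adjusted p = 8.94e-10, adjusted p = 0.0618 with an estimated correlation), including the protease gene Plau by 3.10 ± 0.55 (2.39 without epileptogenic paired B) and Timp1, an inhibitor of matrix metalloproteinases, by 1.47 ± 0.30. With single arrays left out, the number that rose was 12 to 18 for microglia, 4 to 8 for complement, 8 to 13 for interferon, 8 to 13 for lysosomes, 3 to 5 for antigen presentation, 2 to 7 for astrocytes and 1 to 6 for the matrix. The microglial median was 1.98 within letter A and 1.86 within letter B, and the astrocytic median 1.35 and 1.28. Means per array of each of these 7 lists separated the groups, with an exact permutation p of 0.0286, the smallest possible (0.0366 adjusted). This was not particular to them. Most other lists separated the groups with the same p, among them cytokines, endothelium, potassium channels, cholesterol biosynthesis and ribosomal proteins. The permutation takes the 8 arrays as interchangeable, although arrays of the same letter deviated together. With only the 18 splits that put 2 arrays of each letter on either side, no p under 0.05 could be reached.

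Lists of neuronal genes had lower medians in epileptogenic rats. Of 16 excitatory neuron genes 3 fell, Neurod6 with a log2 change of -1.33 ± 0.29 (SE), Lmo3 with -1.16 ± 0.23 and Neurod1 with -1.10 ± 0.24 (4 adjusted over the list alone, 8 with the block; median -0.74, camera adjusted p = 2.54e-05, adjusted p = 0.0618 with an estimated correlation). The vesicular glutamate transporter gene Slc17a7 showed -0.85 ± 0.44 and did not pass (adjusted p = 0.341). Of 14 interneuron genes only Calb2, which encodes calretinin, fell, with -1.34 ± 0.24 (2 adjusted over the list alone, 2 with the block; median -0.39, camera adjusted p = 0.0142, adjusted p = 0.109 with an estimated correlation). The GABA-synthesising enzyme gene Gad1 showed -0.42 ± 0.28 (adjusted p = 0.466) and the neuropeptide gene Npy -0.24 ± 0.36 (adjusted p = 0.775).

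Receptor lists for the main inhibitory and excitatory transmitters had negative medians as well. Gabra5 and Gabrb2 fell, with log2 changes of -1.16 ± 0.20 (SE) and -1.02 ± 0.17, which made 2 of 9 GABA-A receptor subunits (3 adjusted over the list alone, 4 with the block; median -0.55, camera adjusted p = 0.00107, adjusted p = 0.0620 with an estimated correlation). Gria3, an AMPA receptor subunit gene, fell, with -1.05 ± 0.22, as the only one of 13 ionotropic glutamate receptor genes (7 adjusted over the list alone, 7 with the block; median -0.83, camera adjusted p = 4.74e-05, adjusted p = 0.0618 with an estimated correlation). None of 6 metabotropic glutamate receptor genes passed (1 adjusted over the list alone, 1 with the block; median -0.45), and their camera adjusted p was 0.0602 without and 0.0480 with the block, against an adjusted p = 0.149 and 0.196 with an estimated correlation. Grm5 had a log2 change of -0.70 ± 0.20 (adjusted p = 0.101, 0.0168 with the block).

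Channel and synapse lists had negative medians, and few or none of their genes passed. Scn2a, a neuronal sodium channel gene, fell, with a log2 change of -0.87 ± 0.16 (SE), as 1 of 17 sodium, calcium and HCN channel genes (4 adjusted over the list alone, 6 with the block; median -0.47, camera adjusted p = 0.000147, adjusted p = 0.0618 with an estimated correlation). None of 26 potassium channel genes passed in limma, alone or over the list (9 with the block), at a median of -0.52 (camera adjusted p = 0.000305, adjusted p = 0.146 with an estimated correlation); Kcnip4 showed -0.89 ± 0.23 (adjusted p = 0.0734, 0.00313 with the block). Of 19 synaptic vesicle genes, Bsn and Syn2 fell, with -1.08 ± 0.20 and -0.97 ± 0.19 (9 adjusted over the list alone, 12 with the block; median -0.54, camera adjusted p = 1.10e-06, adjusted p = 0.0618 with an estimated correlation). In the postsynaptic density 0 of 21 genes passed (0 over the list alone, 9 with the block; median -0.53, camera adjusted p = 2.08e-05, adjusted p = 0.0618 with an estimated correlation), Dlgap1 showing -0.93 ± 0.25 (adjusted p = 0.0797, 0.00126 with the block). With single arrays left out, the number that fell was 0 to 1 for excitatory neurons, interneurons, ionotropic glutamate receptors, sodium, calcium and HCN channels, neuropeptides and synaptic vesicle release, and 0 to 2 for GABA-A receptor subunits. In cytoskeleton and axon growth 0 of 33 passed (0 over the list alone, 9 with the block; median -0.42, camera adjusted p = 0.00107, adjusted p = 0.0618 with an estimated correlation), Gap43 showing -0.66 ± 0.18 (adjusted p = 0.0834, 0.00899 with the block).

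Signalling lists were mixed. Fos was the only 1 of 26 immediate early genes to pass (2 higher and 1 lower adjusted over the list alone, 5 and 1 with the block; median 0.07, camera adjusted p = 0.0956). Among 23 growth factors, Igf1 rose by 2.44 ± 0.32 (log2, SE) and Ccn3 fell, with -1.33 ± 0.22 (2 higher and 5 lower adjusted over the list alone, 2 and 5 with the block; median -0.11, camera adjusted p = 0.778), while Bdnf showed -0.11 ± 0.31 (adjusted p = 0.887). Of 24 neuropeptide and receptor genes only Trhr fell (3 adjusted over the list alone, 6 with the block; median -0.32, camera adjusted p = 0.00568, adjusted p = 0.146 with an estimated correlation). Of 28 fear learning genes only Prkar2b, a regulatory subunit of protein kinase A, fell, with -0.86 ± 0.18 (1 higher and 4 lower adjusted over the list alone, 4 and 6 with the block; median -0.19, camera adjusted p = 0.253). With single arrays left out, 0 to 1 immediate early genes rose. In these fits 1 growth factor rose and 0 to 2 fell. Of the fear learning genes 0 to 1 rose and 0 to 1 fell.

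Metabolic and stress lists differed in direction. No gene of 15 in cholesterol biosynthesis passed (4 lower adjusted over the list alone, 8 with the block; median -0.58, camera adjusted p = 3.11e-05, adjusted p = 0.109 with an estimated correlation), Msmo1 showing -0.89 ± 0.21 (log2, SE; adjusted p = 0.0550, 0.00571 with the block). None of 31 oxidative phosphorylation genes passed, alone or with the block (median -0.12, camera adjusted p = 0.122). Of 24 ribosomal protein genes Rplp0 rose by 1.00 ± 0.21 (1 adjusted over the list alone, 6 with the block; median 0.35, camera adjusted p = 1.32e-06, adjusted p = 0.133 with an estimated correlation). In heat shock and oxidative stress 3 of 27 rose, Hspb1, the haem-degrading enzyme gene Hmox1 by 1.64 ± 0.27 and Gpx1 by 1.16 ± 0.22 (6 adjusted over the list alone, 7 with the block; median 0.05, mean 0.43, camera adjusted p = 0.0325, adjusted p = 0.109 with an estimated correlation). With single arrays left out, the number that rose was 1 to 4 for heat shock, 0 to 1 for cell death and 0 in each fit for ribosomal proteins. Among 17 cell death genes the inflammatory caspase gene Casp4 rose by 1.60 ± 0.26 (4 adjusted over the list alone, 4 with the block; median 0.36, camera adjusted p = 0.00216, adjusted p = 0.0620 with an estimated correlation).

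Markers of other cell types and signs of RNA quality were read beside these groups. Of 18 oligodendrocyte genes Aspa and Bcas1 rose, by 1.74 ± 0.26 and 0.79 ± 0.17 (log2, SE; 4 adjusted over the list alone, 6 with the block; median 0.51, camera adjusted p = 2.08e-05, adjusted p = 0.170 with an estimated correlation). None of 15 endothelial and mural genes passed (4 adjusted over the list alone, 4 with the block; median 0.38, camera adjusted p = 0.0106, adjusted p = 0.0913 with an estimated correlation). Of 12 meningeal and fibroblast genes Bgn rose by 1.76 ± 0.32 (6 adjusted over the list alone, 6 with the block; median 1.16, camera adjusted p = 1.99e-05, adjusted p = 0.146 with an estimated correlation). With single arrays left out, the number that rose was 1 to 3 for oligodendrocytes and 0 to 4 for meninges. The striatal and central amygdala list (14 genes, median -0.14, camera adjusted p = 0.798; 1 higher with the block) and the choroid plexus list (11 genes, median 0.29, camera adjusted p = 0.233) had no member that passed, and of the blood cell list only Hbb was measured, at -1.02 ± 0.53 (-0.35 without epileptogenic unpaired B). The 3' to 5' signal ratio differed between the groups by 0.29 on the log2 scale for actin (exact permutation p = 0.743) and 0.15 for Gapdh (exact permutation p = 0.600).

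Camera with the preset correlation called 24 of 32 lists, 13 higher and 11 lower (25 with the block), and fry 24 (25 with the block). With an estimated correlation 0 of 32 were called, the smallest adjusted p being 0.0618 without and 0.139 with the block.

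**Figure D2:**
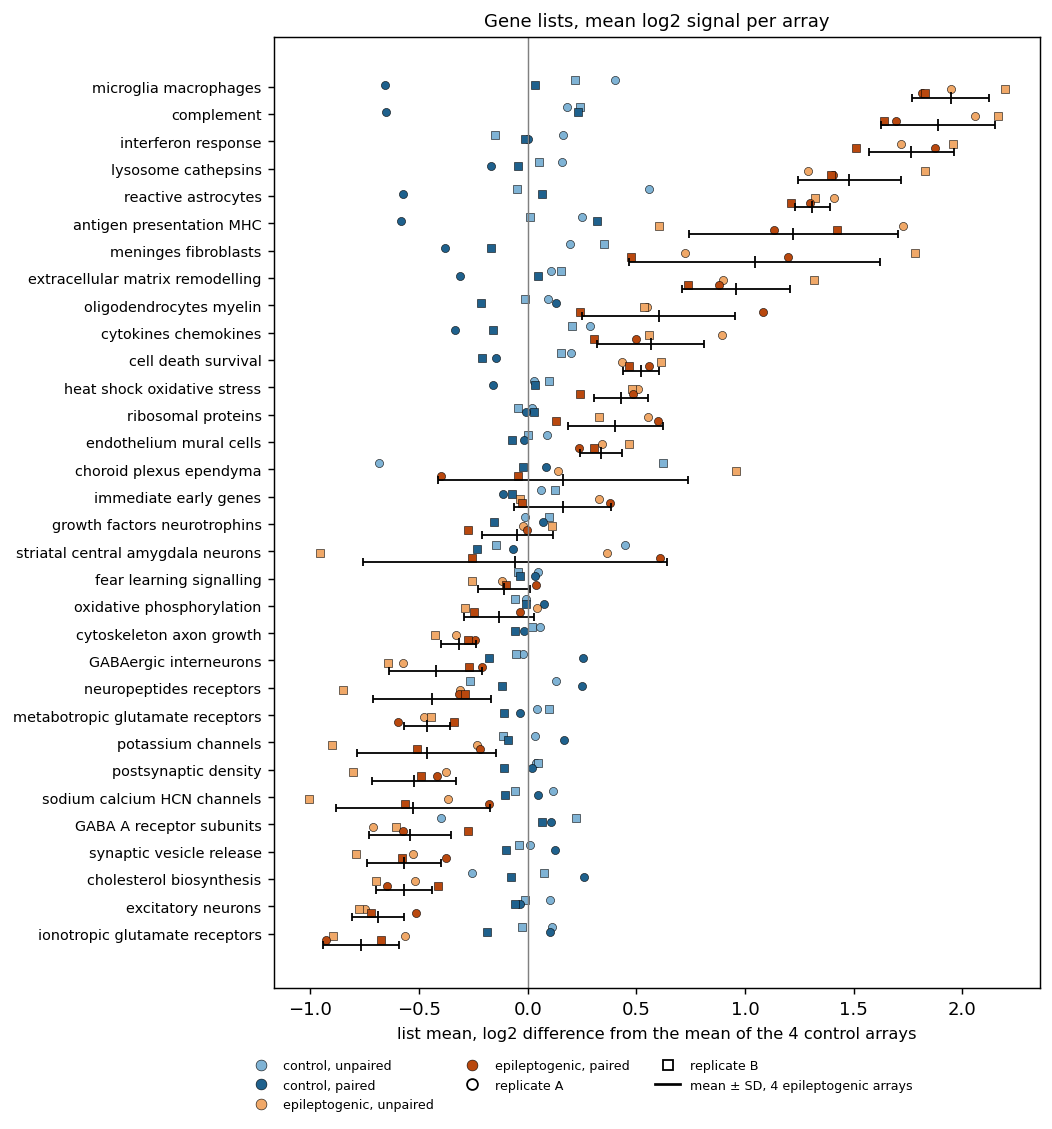
Mean log2 signal per array of the genes of each list, as the difference from the mean of the 4 control arrays (points; colours give the group, circles letter A and squares letter B), with bars for the mean ± SD of the 4 epileptogenic arrays. The 4 epileptogenic arrays lie between 1.82 and 2.20 for microglia and macrophages, and the 4 control arrays between -0.66 and 0.40.

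Among rats with unpaired training, the comparison asks what epileptogenesis does without learned association of tone and shock. Slfn4 rose by 4.85 ± 0.72 (log2, SE; adjusted p = 0.0443) from a control mean under the filter level (3.88 without epileptogenic unpaired B), Fcrl2 by 3.60 ± 0.54, Ifgga2l1 by 3.22 ± 0.30, Fcgr2b by 3.05 ± 0.50, Rsad2 by 2.96 ± 0.35 and the complement gene C1qa by 2.85 ± 0.29, with 2 arrays per group. Gfap rose by 2.53 ± 0.40 (adjusted p = 0.0499). Nrarp fell, with -2.27 ± 0.33, as did the presynaptic scaffold gene Bsn with -1.75 ± 0.28 and the neuronal transcription factor gene Myt1l with -1.57 ± 0.24. Of 26 microglial genes 5 rose (21 adjusted over the list alone, 18 with the block; median 1.64, adjusted p = 0.0585 with an estimated correlation), 5 of 16 lysosomal genes (12 adjusted over the list alone, 11 with the block; median 1.43, adjusted p = 0.0585 with an estimated correlation) and 3 of 19 interferon response genes (14 adjusted over the list alone, 14 with the block; median 1.87, adjusted p = 0.0585 with an estimated correlation).

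In this comparison limma called 59 probe sets, 54 higher and 5 lower, and 1306 with the block (633 higher, 673 lower). Without the intensity trend it called 0, so each call named above depends on the trend. Camera called 24 of 32 lists with the preset and 0 with the estimated correlation. The count was 0 without control unpaired A, without control unpaired B, without epileptogenic unpaired A or without epileptogenic unpaired B, each of which leaves 1 array in a group, and 34, 30, 17 and 17 without control paired A, control paired B, epileptogenic paired A and epileptogenic paired B.

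Among rats with paired training, the comparison asks what epileptogenesis does in fear-conditioned animals. Hspb1 rose by 4.65 ± 0.77 (log2, SE; adjusted p = 0.0421), Serping1 by 3.90 ± 0.67, Rsad2 by 3.84 ± 0.35, Fcgr2b by 3.67 ± 0.50, Fcrl2 by 3.55 ± 0.54 and Ifgga2l1 by 3.54 ± 0.30, with 2 arrays per group. Gfap rose by 3.12 ± 0.40 (adjusted p = 0.0240). Ngb and Nrarp fell, with -3.62 ± 0.57 and -2.24 ± 0.33, and the lower group of Hspb1 and of Ngb lay under the filter level. Without control paired A the changes were 3.93 for Hspb1, 2.60 for Serping1, 2.84 for Fcgr2b, 2.90 for Fcrl2 and -2.95 for Ngb, and that of Fcrl2 was 2.87 without epileptogenic paired B. Of 26 microglial genes 9 rose (24 adjusted over the list alone, 22 with the block; median 2.09, adjusted p = 0.0660 with an estimated correlation), 6 of 16 lysosomal genes (13 adjusted over the list alone, 13 with the block; median 1.56, adjusted p = 0.0826 with an estimated correlation) and 3 of 19 interferon response genes (14 adjusted over the list alone, 13 with the block; median 1.53, adjusted p = 0.0660 with an estimated correlation).

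Here limma called 99 probe sets, 97 higher and 2 lower, and 860 with the block (642 higher, 218 lower). It called 0 without the intensity trend, so the calls named for paired training depend on the trend as well. Camera called 23 of 32 lists with the preset and 0 with the estimated correlation. The count was 0 without control paired A, epileptogenic paired A or epileptogenic paired B, 51 without control paired B, 61 without epileptogenic unpaired B, 66 and 67 without control unpaired B and control unpaired A, and 74 without epileptogenic unpaired A.

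The effects under the 2 protocols share no array. Across 10364 genes their log2 changes had a Pearson correlation of 0.618 and a Spearman correlation of 0.543, genes not being independent replicates. The size of this correlation depended on the filter, being lower without it and higher with the stricter one. Gfap, Rsad2, Fcgr2b, Fcrl2, Ifgga2l1 and Nrarp passed in the same direction under both. In all, 40 probe sets were called higher under both protocols against 0.281 for independent lists of these sizes, and 1 was called lower under both against 0.000537. Both tests took the spread of a probe set from the same fit. The calls are therefore not independent, and these expected numbers are only a rough guide.

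**Figure D3:**
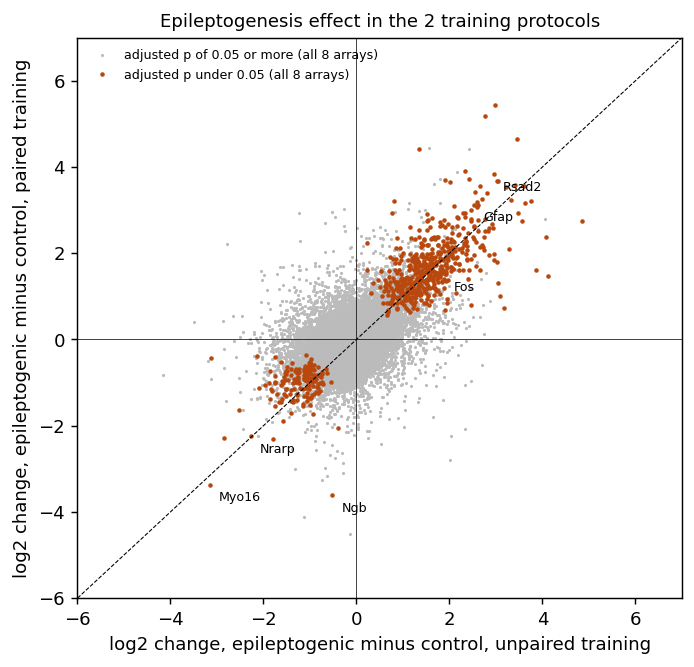
Log2 change from control to epileptogenic arrays under unpaired training (horizontal axis) against that under paired training (vertical axis), with each point a probe set, coloured where it passed in the comparison of all 8 arrays, and a dashed line for equal change. Rsad2, at 2.96 and 3.84, and Nrarp, at -2.27 and -2.24, lie on opposite sides of the cloud.

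The comparison of 4 paired with 4 unpaired arrays addresses learned association of tone and shock. No gene passed, and those with the smallest p are given as values only. Supt6h had a log2 difference of 0.71 ± 0.21 (SE), Strada 0.72 ± 0.26 and Lnx1 0.71 ± 0.23, and Pmfbp1 -1.48 ± 0.36, Lrfn1 -0.89 ± 0.22 and Odad3 -2.03 ± 0.51, the paired means of Pmfbp1 and Odad3 lying under the filter level. Learning-related immediate early genes showed -0.10 ± 0.28 (Fos) and -0.36 ± 0.47 (Arc), and the neurotrophin gene Bdnf 0.26 ± 0.31, each with an adjusted p of 1.00. Microglial genes had a median log2 difference of -0.44 (camera adjusted p = 4.86e-09, adjusted p = 0.289 with an estimated correlation) and complement genes -0.41 (camera adjusted p = 1.28e-05, adjusted p = 0.289 with an estimated correlation). Meningeal genes stood at -0.46, astrocytic genes at -0.33 and matrix genes at -0.18 (camera adjusted p = 0.000316, 0.000317 and 0.000357, adjusted p = 0.289 with an estimated correlation for each), and lysosomal genes at -0.19 (camera adjusted p = 0.00588, adjusted p = 0.315 with an estimated correlation). The medians for neuropeptides and interneurons were 0.24 and 0.17 (camera adjusted p = 0.000357 and 0.00186, adjusted p = 0.289 with an estimated correlation for each).

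Limma called 0 probe sets, with 214 (1.15%) at an unadjusted p under 0.05, and 0 with the block, with 730 (3.92%). Camera called 13 of 32 lists (7 higher, 6 lower), camera with an estimated correlation 0 and fry 0. Camera called 2 lists without control paired A and 5 without epileptogenic unpaired B. Within letters A and B limma called 0 and 0 probe sets, with 139 and 277 at an unadjusted p under 0.05. The list medians were unlike between letters for astrocytes (-0.68 in A, 0.02 in B) and meninges (0.10 and -0.97), and alike in sign for microglia (-0.45 and -0.20). In simulated data 5.33% of 2-fold and 60.7% of 4-fold changes were recovered without the block, and 64.0% and 86.7% with it. Changes of 2-fold or less in single genes were therefore not reliably detectable with these arrays, and without the block many 4-fold changes were missed too.

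Within control rats the same question concerns learning in animals without seizures. Gfer (2.24 ± 0.62, log2, SE), Fuom (1.77 ± 0.51) and B4galnt4 (1.45 ± 0.44) had the smallest p among positive differences and Nid1 (-1.25 ± 0.25), Cd244l1 (-1.37 ± 0.33) and Rpe65 (-2.41 ± 0.62) among negative ones, with 2 arrays per group, and none passed. The lower group of Gfer and of Rpe65 lay under the filter level, and Gfer showed 1.64 without control unpaired A. Limma called 0 probe sets, with 313 (1.68%) at an unadjusted p under 0.05 and 919 (4.93%) with the block, which also called 0. Without control paired B, 2 passed. Camera called 4 lists, all lower: astrocytes, microglia, complement and meninges, and 2 with the block, where complement (adjusted p = 0.0510) and meninges (adjusted p = 0.0588) were lost. The estimated correlation gave an adjusted p = 0.677 for each, and fry called 0. Control paired A stood apart, with list means per array of -0.57 for astrocytes, -0.66 for microglia and -0.65 for complement against 0.06, 0.04 and 0.23 in control paired B, and camera called 0 lists without control paired A and 9 without control paired B.

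Within epileptogenic rats it concerns learning during epileptogenesis. Fgfrl1 (2.22 ± 0.51, log2, SE), Dxo (2.35 ± 0.56) and the chromatin remodeller gene Smarca2 (1.04 ± 0.26) had the smallest p among positive differences and Fbxo2 (-1.40 ± 0.32), Pmfbp1 (-2.09 ± 0.50) and the autophagy gene Atg7 (-1.52 ± 0.39) among negative ones, with 2 arrays per group, and none passed. The lower group of Dxo and of Pmfbp1 lay under the filter level. Limma called 0 probe sets, with 228 (1.22%) at an unadjusted p under 0.05 and 933 (5.01%) with the block, which also called 0. Camera called 15 lists (10 higher, 5 lower; 14 with the block) and 0 with an estimated correlation (smallest adjusted p = 0.270), and fry called 0. With the preset correlation camera called 0 lists without epileptogenic unpaired B, 4 without epileptogenic paired B and 9 without epileptogenic paired A. Across genes the training effects in control and epileptogenic rats had a Pearson correlation of -0.0506.

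The interaction asks whether epileptogenic rats respond otherwise to paired training than control rats. Nid1, a basement membrane gene, showed a log2 interaction of 2.00 ± 0.35 (SE), with means of 7.51 ± 0.13 (SD, n = 2) in control paired and 9.74 ± 0.13 in epileptogenic paired arrays. Smarca2 showed 1.87 ± 0.36, Cd244l1 2.17 ± 0.47, Ngb -3.10 ± 0.80 (-2.43 without control paired A; epileptogenic paired mean under the filter level), Fbxo2 -1.54 ± 0.45 and the mitochondrial protease gene Lonp1 -1.45 ± 0.45. None passed (adjusted p = 1.00 for Nid1, 0.120 with the block). Limma called 0 probe sets, with 274 (1.47%) at an unadjusted p under 0.05 and 1056 (5.67%) with the block, which also called 0. Camera called 1 of 32 lists, striatal and central amygdala neurons (median 0.66, camera adjusted p = 0.00648, adjusted p = 0.722 with an estimated correlation), and fry called 0. The interaction of the list means was 0.76 within letter A and 0.79 within letter B, and the camera adjusted p with the block 0.000946 (0.767 with an estimated correlation). Camera called 0 lists without control unpaired A or epileptogenic unpaired B, 3 without control unpaired B, 9 without epileptogenic unpaired A, and 2 without control paired A, control paired B or epileptogenic paired B. A difference between the protocols in the effect of epileptogenesis was therefore not shown for any gene.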

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

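No explanation was tested for the result below, which was found by a comparison planned beforehand. The interaction of training and epileptogenesis had a median log2 value of 0.66 over 14 genes of striatal and central amygdala neurons, with a camera adjusted p = 0.00648, but an adjusted p = 0.722 with an estimated correlation and fry adjusted p = 0.909; among the members, Foxp1 showed 1.41 and Drd2 2.40, while Foxp2 showed -0.53 (chosen after their values were seen). The mean of this list per array, relative to the control mean, was 0.36 on epileptogenic unpaired A and -0.96 on epileptogenic unpaired B, and 0.61 and -0.25 on epileptogenic paired A and B, but the interaction of these means was 0.76 within letter A and 0.79 within letter B, and with the block the camera adjusted p was 0.000946 (0.767 with an estimated correlation). It stood out because the test of the difference between the training effects in epileptogenic and control rats passed for this list under the preset correlation.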

How the results depend on the processing

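The fits within letter A or B were chosen after the data were seen. Across the alternatives no named gene or list passed in opposite directions. The balance of probe sets did reverse with the block for epileptogenic against control, from 523 higher and 154 lower to 1411 and 1611. Under unpaired training it went from 54 and 5 to 633 and 673. Of epileptogenic against control, 677 probe sets became 330 without the intensity trend, 1261 in a 2-group fit, 1321 within letter B, 3022 with the block and 224 to 435 with arrays left out. Under unpaired training, 59 became 98 with quantile normalization, 25 with median centring, 103 with the stricter filter, 13 with only the groups compared, 0 without the trend, 1306 with the block and 0 to 34 with arrays left out. Under paired training, 99 became 64 with only the groups compared, 0 without the trend, 860 with the block and 0 to 74 with arrays left out. Training in control rats gave 0 to 2 probe sets with arrays left out (2 without control paired B). The other training comparisons stayed at 0.

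Lists called were 2 for training in control rats without the filter and 2 with the block (0 to 9 with arrays left out), and 6 for training in epileptogenic rats without the filter (0 to 15). For training in all rats they were 2 to 16. For the interaction they were 2 with quantile normalization, 2 with the stricter filter, 3 with the mean of a gene's probe sets and 0 to 9 with arrays left out. The correlation between protocols was 0.335 without the filter, 0.735 with the stricter filter and 0.491 to 0.601 with arrays left out. Fewer or dimmer probe sets tested, fewer arrays and a letter removed from the residual spread follow from how these alternatives are built; otherwise the cause was not tested. Quantile normalization moved the median of all tested probe sets under unpaired training from -0.14 to -0.04. The 135 values of named genes over all comparisons include many that did not pass in the main fit and so had no call to lose. Among the rest, 42 no longer passed without the trend, 13 with median centring and 7 with quantile normalization. Leaving out single arrays ended calls of named genes as well. A change in sign without a call occurred for 4 of 2133 values of named genes, in Arc, Bdnf and Npy. Of 544 list values 7 changed sign, including heat shock, at -0.02 without control unpaired A. In addition, the block let 12 genes of epileptogenic against control and the metabotropic glutamate receptor list pass, and of the training lists it ended the camera call of synaptic vesicle release (all rats), complement and meninges (control rats) and fear learning (epileptogenic rats) and added choroid plexus (all rats). Under the 2 protocols taken singly it added oxidative phosphorylation (paired) and metabotropic receptor, striatal and choroid plexus lists (unpaired), and it changed no other camera call. Without detection calls, signal over background limits what can be said of the genes with a group under the filter level.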

Other observations

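The gene lists of this paragraph and the next were chosen after the data were seen, as were the tests on cell share, RNA quality, meninges and spike-in controls, and these lists are adjusted together with the earlier ones, over 38 lists. Genes of lipid transport and storage rose in epileptogenic rats, 9 of 20 measured (12 adjusted over the list alone, 12 with the block; median log2 change 0.82, camera adjusted p = 1.03e-07, adjusted p = 0.0629 with an estimated correlation, 0.148 with the block too). They included the sterol esterifying enzyme gene Soat1 (2.20 ± 0.40, SE), the cholesterol exporter gene Abca1 (1.86 ± 0.22), the lipid droplet gene Plin2 (1.70 ± 0.24) and the sterol-oxidising enzyme gene Ch25h (1.60 ± 0.30). Of 15 annexin and S100 genes, calcium-binding proteins, 7 rose (9 adjusted over the list alone, 9 with the block; median 0.89, camera adjusted p = 1.00e-07, adjusted p = 0.0629 with an estimated correlation, 0.155 with the block too), led by Anxa3 (2.43 ± 0.26) and S100a4 (1.70 ± 0.28). Olr1, Npc2, Fabp7 and S100a6 of these lists also stand in lists of the report.

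Of 21 cell cycle genes, Top2a (1.99 ± 0.44, log2, SE) and Aurka (1.61 ± 0.37) rose, from control means under the filter level (8 adjusted over the list alone, 9 with the block; median 0.59, camera adjusted p = 6.60e-05, adjusted p = 0.124 with an estimated correlation). The serotonin receptor gene Htr2c fell by 1.13 ± 0.19 (adjusted p = 0.0164), as 1 of 18 monoamine, acetylcholine and related receptor genes (1 adjusted over the list alone, 2 with the block; median -0.27, camera adjusted p = 0.0774). Of 15 Notch signalling genes only Nrarp fell (3 higher and 1 lower adjusted over the list alone, 3 and 1 with the block; camera adjusted p = 0.552). None of 15 glycolysis genes passed (0 adjusted over the list alone, 5 lower with the block; median -0.30, camera adjusted p = 0.0158, adjusted p = 0.148 with an estimated correlation). Of the T and NK cell genes 4 were measured, with a median of -0.24 and no test.

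The means of the microglial, complement, interferon and lysosomal lists were higher in all 4 epileptogenic than in all 4 control arrays. The real split of the 8 arrays called 1261 probe sets in a 2-group fit, 1 of 35 splits as large, the highest other calling 996. That is the smallest share this test can give, and it does not exclude chance. The other split parts letter A from letter B, which points to a structure of the samples by letter, so the splits are not interchangeable. Among the 18 splits with 2 arrays of each letter on either side, the highest other called 0. So few splits cannot bring the share of the real one under 0.05. A larger share of every non-neuronal cell type would raise their markers alike, but the microglial list rose by 1.48 more on the log2 scale than the mean of the oligodendrocyte and endothelial lists (exact permutation p = 0.0286). The lists were compared after their changes were seen, so this p-value is no independent test. Both other lists rose as well, by 0.60 and 0.34 in the mean, so a larger non-neuronal share stays open as a part of the rise. On RNA quality, the rise was 2.01 ± 0.30 (SE) with the actin and Gapdh 3' to 5' ratios as covariates and 1.95 ± 0.25 without. Those ratios differed little between the groups (0.29 and 0.15 on the log2 scale). They therefore do not account for the rise, but quality that they do not reflect was not tested. This test replaced an earlier one, on whether the ratios of the groups overlapped, after its outcome was known. Meningeal tissue as the whole source would raise meningeal genes at least as much, but the microglial list rose by 0.90 ± 0.26 more; its most abundant genes Igf2, Col1a1 and Lum showed 0.67 ± 0.42, 1.51 ± 0.36 and 1.95 ± 0.46 and did not pass, all 12 were above the filter level in control arrays, 3 also stand in other lists, and a meningeal share in the matrix genes stays open. A response of microglia to status epilepticus may underlie the rise, as more cells or as more transcript per cell, which was not tested. Only the epileptogenic rats were stimulated, and the tissue came from the amygdala on the side of the electrode. Local effects of the stimulation can therefore not be told apart from those of status epilepticus.

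Paired and unpaired arrays gave fewer small p-values than chance alone, 1.15% of probe sets under 0.05, and the real split called 0. Any split calls at least 0, so the count of 35 of 35 splits was fixed beforehand and says nothing about chance (highest other 1261). A difference shared by arrays of the same letter could widen the residual spread, and with the letter as a block the share was 3.92%. A weak effect of training stays open, since 2-fold changes were recovered in 5.33% of simulated cases without the block and 64.0% with it, and 4-fold changes in 60.7% and 86.7%, while the blocked fit of the real data also called 0.

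Arrays with the same letter deviated together, and 3263 probe sets differed between the letters, 1506 higher in A and 1757 higher in B. A hybridisation or labelling batch is a candidate explanation: the 18 spike-in probe sets, which do not come from rat RNA, were higher on the A array in 4 of 4 groups, by 0.43 on the log2 scale on average (0.66, 0.40, 0.51 and 0.14). The median signal was also higher on A in 4 of 4 groups (43.2, 39.5, 34.9 and 36.6 against 33.8, 29.0, 32.2 and 30.4 on B). Whether the spike-in difference only follows that shift of whole arrays was not tested. The actin 3' to 5' log2 ratio was higher on B in 4 of 4 groups (4.42, 4.30, 3.82 and 4.45 on B against 1.87, 3.21, 3.63 and 3.07 on A) and that of Gapdh was not, so a difference in RNA quality or amplification stays open too. No biological explanation was tested, since the labels do not say what the letters mean, and a difference between the pooled rats stays open.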
